A study of Mus musculus with 2 samples.

How the data were processed

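Single-cell RNA sequencing (10x Genomics) was measured in 2 libraries of mouse striatal cells. Per the labels' protocols, Aldh1l1-Ai14 mice, whose astrocytes carry a tdTomato reporter after tamoxifen, received bilateral injections of a lentivirus with the human GFAP promoter. The virus carried DLX2 and GFP in 5 mice (DLX2 library) or GFP alone in 4 mice (control library). Brains were taken 4 weeks later, digested with papain, and tdTomato-positive cells were sorted. The mice of a group were pooled, so each group has 1 library, and the sexes of the mice are not given in the sources used here. The public embryonic sets that the series design mentions were not used here.

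The deposited matrices hold UMI counts per gene and cell barcode, made with Cell Ranger per the submitters' processing notes, which list versions 3.0.2 and 3.1.0 without their roles and the build mm10. Per the file headers the matrices are Matrix Market integer tables, and they are the filtered kind, limited to barcodes called as cells. Of 31055 features, 2 are added sequences: the lentiviral vector with Dlx2, IRES and GFP, and tdTomato with its WPRE and polyadenylation signal. The other 31053 are Ensembl genes. Of their IDs, 30934 are in the GENCODE vM21 annotation of GRCm38 (mm10), from which positions are given, and 30468 carry the same symbol there. Parts of the added vector sequence are shared with the control vector, so control cells also give vector UMIs.

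Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs. Doublets were called in each library with Scrublet in scanpy 1.11.5 and removed. Where its own threshold marked under 0.5% of cells, the rule was to remove the highest scores up to 0.8% per 1000 barcodes. UMIs were scaled to 10000 per cell and log-transformed. Both libraries were clustered together without correction between them, on 2000 variable genes per library, 30 principal components, 15 neighbours and Leiden resolution 1. From clustering, 127 genes were left out: Dlx2, the added sequences and the sex-linked, mitochondrial and ribosomal protein genes. Clusters were named from 17 fixed sets of cell type markers. A name needed at least 3 enriched markers, detected in at least 25% of the cluster at a level at least 2-fold above the other cells, and at least 1 own marker among its 20 leading genes. It also needed at least 5 enriched markers or 2 own markers among the 10 leading genes, and no other set with more markers among those 10. Clusters that missed any of these conditions stayed unnamed, and in the alternatives also shallow clusters without an own marker among the 10. The details of this naming rule were adjusted after the clusters were seen: neuroblasts and neurons, and microglia and border macrophages, were not set against each other, and progenitors needed a marker outside the cell cycle. The name Igfbp4 cluster is a handle for 1 cluster that the rule left unnamed, since fibroblast markers led it, and it is counted among the neural cells.

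For each class with at least 50 cells in each library, and for all kept cells, UMIs were summed per library and expressed as CPM, which scales every sum to a common total. The DLX2 over control ratio has an exact conditional 95% interval, and shares of cells have exact Clopper-Pearson 95% intervals. With 1 library per group no test of a difference between groups was made, since cells are not replicates. The intervals and the limits at 0 (3 counts) cover counting error only. Genes are counted by size alone: a ratio of at least 2 either way, with at least 20 CPM and 30 UMIs in the higher library. Genes named individually are the 12 highest and 12 lowest in astrocytes, and 6 and 6 in every other class and in all cells, among those that pass this rule, ranked by the interval bound nearest to 1. Mitochondrial, ribosomal protein, sex-linked and unnamed predicted genes were left out of naming. The 2 highest and 2 lowest members of each list could also be named.

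For 23 gene lists, the median log2 ratio (0.5 UMI added to each sum) was taken over members with at least 30 UMIs in both libraries together. It was placed among 10000 random lists of the same size drawn in 20 bins of CPM, as a description of these libraries, and members at least 1.5-fold higher or lower were counted. Shares of cells with a UMI of a gene were taken after thinning each cell to 2500 UMIs, which left 5185 DLX2 and 4401 control cells. These lists, rules and main settings, and most alternatives, were fixed before the data were examined.

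Several steps were chosen after seeing the data. Mixed barcodes were defined as those with at least 10 UMIs, and at least 5% of the level of its own cells, of markers of another of 4 compartments. Cells were split by sex into those with Xist and no UMI of 4 Y-linked genes, and the reverse. Other denominators, a tdTomato filter and leaving out the cell with most UMIs of a named gene were added as alternatives. The alternatives fixed beforehand were other cell filters (200 genes, 500 UMIs and 25%, or 1000, 2000 and 10%), doublets kept, resolutions of 0.5 and 2, each library clustered alone, genes centred within each library, clustering without 269 genes at least 2-fold apart between the libraries in astrocytes, median-of-ratios scaling, equal weight per cell, minimums of 10 and 100 UMIs, means for medians and other thinning depths.

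The size rule was tested on simulated data with the depths of these libraries. Of 50 genes each changed 1.5, 2.5, 4 and 8-fold, it passed 3, 35, 42 and 45 in astrocytes and 2, 37, 41 and 46 in neuroblasts. Among unchanged genes it passed 87 of 12173 in astrocytes and 139 of 12673 in neuroblasts, and each of these was on the higher side, because the control sums are small. In oligodendrocytes it passed 9 unchanged genes as higher and 23 as lower of 9391, in endothelial cells 10 and 26 of 9799, and 0 in microglia or macrophages and in lymphocytes. Of 100 lists of 20 unchanged genes in astrocytes, 1 fell below the 2.5 percentile and 8 above the 97.5 percentile.

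Python 3.11.15 was used with anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.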

Results

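Each library came from 1 pool of mice: 5 mice for DLX2 and 4 mice for control. The DLX2 library held 6452 barcodes and 42567621 UMIs, and the control library 5075 barcodes and 55334341 UMIs. After filtering and doublet removal, 5622 DLX2 cells (87.1%) with a median of 5372 UMIs and 4648 control cells (91.6%) with a median of 11106 UMIs remained. They formed 31 clusters. No difference between the libraries has a replicate check.

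The first comparison asks where Dlx2 and the reporters were detected, as a check of the labels. Dlx2 (ENSMUSG00000023391, GRCm38 chromosome 2, 71543408 to 71546754), a homeobox factor of ventral forebrain neurogenesis, reached 125 CPM in the DLX2 library and 5.24 CPM in the control library. Its level followed the neuronal lineage cells and not the astrocytes: it was 313 CPM in DLX2 and 490 CPM in control neuroblasts, 221.5 and 281.6 CPM in progenitors, and 5.76 and 4.53 CPM in astrocytes. UMIs on the annotated gene need not come from the vector. The vector sequence was at 309 CPM in DLX2 and 125 CPM in control cells, and tdTomato at 422 and 159 CPM.

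Vector UMIs were common in neuroblasts of the DLX2 library and rare in those of the control library. At a depth of 2500 UMIs, 44.7% of DLX2 neuroblasts (95% interval 42.5% to 46.9%) and 4.76% of control neuroblasts (1.31% to 11.8%) held one. In lymphocytes, which should lack the GFAP promoter's activity, 5.00% and 4.90% did. The median depths of neuroblasts were 3959 and 3610 UMIs, and of lymphocytes 3424 and 3789.5 UMIs. Astrocytes of both libraries held vector UMIs about as often as lymphocytes, at 5.12% and 6.85%. The DLX2 Igfbp4 cluster had 82.8% and DLX2 progenitors 51.9%. In the control library the vector was found in ependymal cells, 69.8%, and in oligodendrocyte precursor cells (OPCs), 71.8%. Endothelial cells held it at 45.2% and 51.9% in DLX2 and control. Other classes of both libraries held it too. Without thinning, among cells with Xist and no Y-linked UMI, 21 of 50 DLX2 and 49 of 66 control oligodendrocytes did. In microglia or macrophages it was 33 of 162 and 855 of 2342. Among cells with Y-linked UMIs and no Xist, oligodendrocytes were at 15 of 23 and 3 of 7. Microglia or macrophages were then at 28 of 63 and 51 of 79. A tdTomato UMI was found in 72.1% of DLX2 and 69.9% of control astrocytes, in 48.5% and 48.8% of neuroblasts, in 53.04% and 47.1% of lymphocytes and in 14.0% and 11.1% of endothelial cells.

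**Figure D1:**
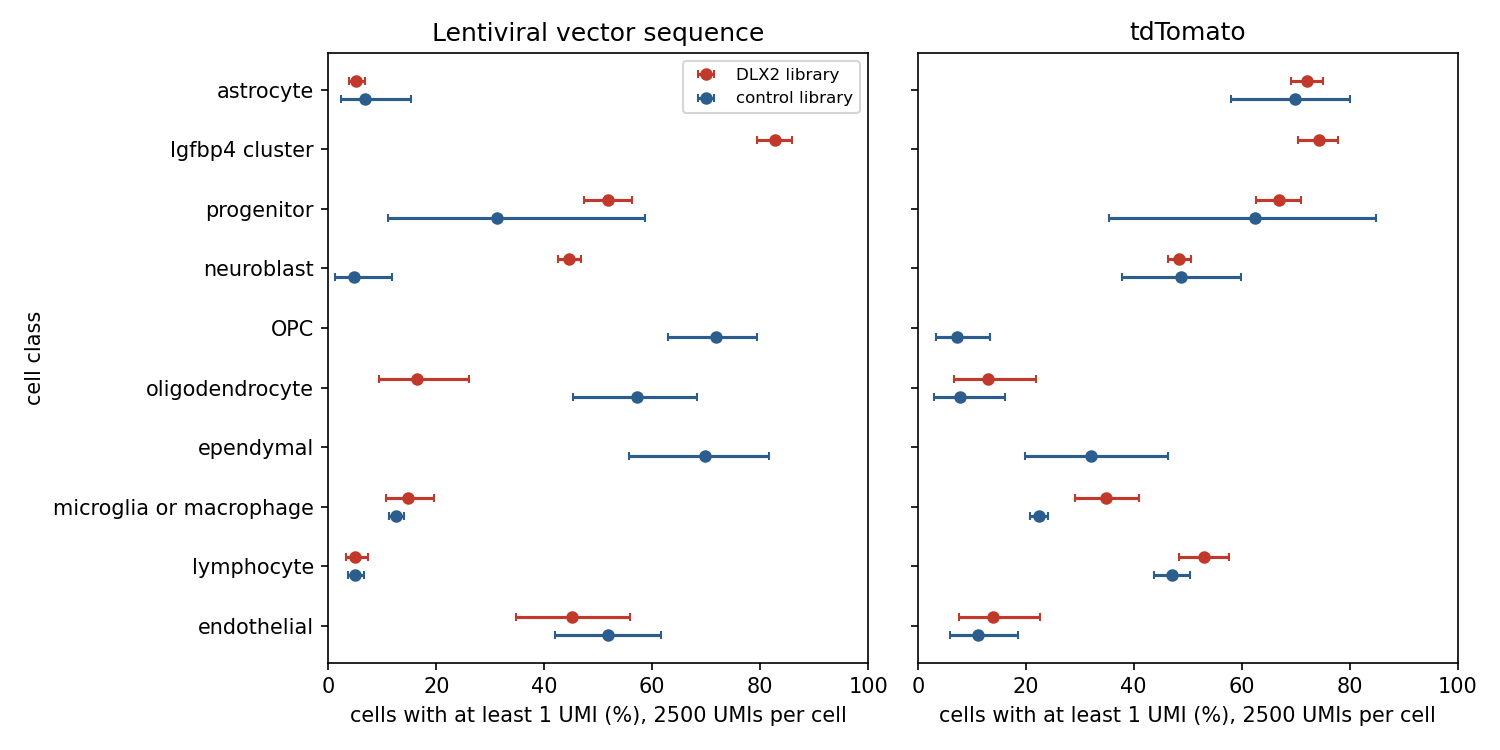
Percentage of cells with a UMI of the vector and of tdTomato by class and library, at 2500 UMIs per cell, with exact 95% intervals. The vector was found in 44.7% of DLX2 and 4.76% of control neuroblasts, and in 5.12% and 6.85% of astrocytes.

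The second comparison asks which cell types made up the sorted cells with and without DLX2 in the vector. Neuroblasts, young neurons that express the microtubule protein Dcx, were the most numerous class of the DLX2 library, with 2197 cells or 39.1% (37.8% to 40.4%), against 91 cells or 1.96% (1.58% to 2.40%) in control. Progenitors, which express the growth factor receptor Egfr, were 9.11% and 0.344% of cells. Astrocytes were 16.9% (952 cells) and 1.70% (79 cells). OPCs were 0.142% of DLX2 and 2.67% of control cells, and ependymal cells were 0 of 5622 DLX2 cells, which allows up to 0.0534%, and 1.14% of control cells. Microglia or macrophages, the immune cells of the brain and its borders, made up 5.05% of DLX2 and 54.2% of control cells, and lymphocytes 10.7% and 22.2%.

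These shares are those of cells sorted for tdTomato and of libraries whose median depths differ, and a class that takes more of one library lowers all others there. As ratios of the DLX2 over the control share, neuroblasts were at 19.96 (16.2 to 24.9), progenitors at 26.5 (16.1 to 46.6) and astrocytes at 9.96 (7.91 to 12.7). The control over DLX2 ratio was 18.7 (9.22 to 44.4) for OPCs and 10.7 (9.49 to 12.2) for microglia or macrophages. Oligodendrocytes (0.913, 0.663 to 1.26), mural cells (1.34, 0.755 to 2.43) and neurons (7 and 10 cells) had intervals that include 1, and endothelial cells were at 0.758 (0.572 to 1.00). The astrocyte ratio was 15.2 under the stricter filter and 21.4 among Xist cells, while over neural cells it was 2.603 (1.90 to 3.66) among Xist cells and 0.2999 (0.197 to 0.476) among cells with Y-linked UMIs. The DLX2 over control ratio of microglia or macrophages was 0.195 with each library clustered alone and 0.0442 with genes centred within each library. The oligodendrocyte ratio was 0.586 at a resolution of 0.5 or with such centring. Over neural cells alone, 4345 and 456, neuroblasts were 50.6% and 19.96%, a ratio of 2.53 (2.05 to 3.16), progenitors 11.8% and 3.51%, astrocytes 21.9% and 17.3%, OPCs 0.184% and 27.2% and oligodendrocytes 1.96% and 16.9%. Over astrocytes, the Igfbp4 cluster, progenitors and neuroblasts alone, neuroblasts were 51.8% and 47.4%, a ratio of 1.09 (0.885 to 1.36), and the astrocyte ratio turned to 0.545 (0.433 to 0.695).

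**Figure D2:**
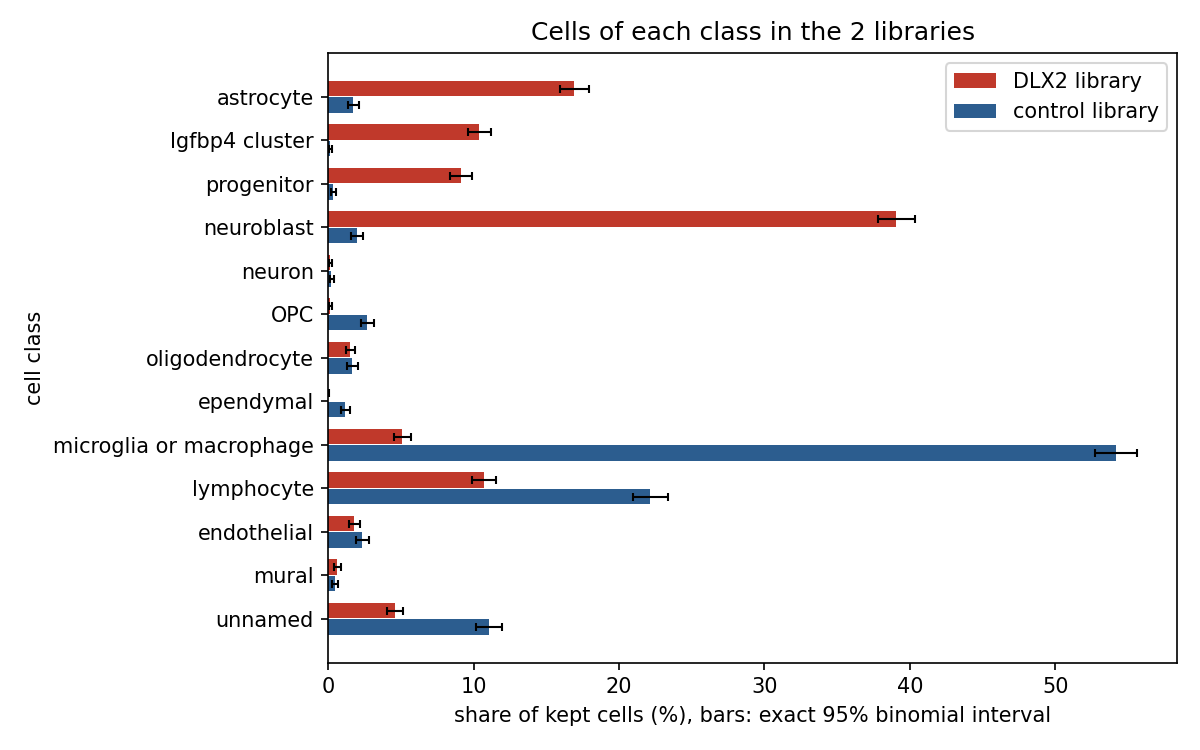
Percentage of kept cells in each class for the DLX2 and the control library, with exact 95% intervals. Neuroblasts were 39.1% and 1.96%, and microglia or macrophages 5.05% and 54.2%.

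The Igfbp4 cluster held 584 DLX2 and 6 control cells, 10.4% and 0.129%. Its leading genes were Crym, Prss56, Igfbp4, Col1a2, Dio2, Edn3 and Ecel1, it was enriched for 9 astrocyte markers such as Slc1a3 and Aldoc, and 96.6% of its DLX2 cells held a vector UMI without thinning. A cluster that comes mostly from 1 library can reflect that library instead of a cell type. Its ratio of shares, 80.5 (36.7 to 220.2), was 26.6 under the stricter filter, 126 with genes centred within each library, 158 without mixed barcodes, which were 3 of its 6 control cells, and 187 at a resolution of 2. Clustering each library alone gave 490 such cells in DLX2 and 0 in control. The DLX2 cells of the Igfbp4 cluster had a median of 9.35% mitochondrial UMIs, against 4.64% over all kept DLX2 cells. Under the stricter filter, which also cuts at 10% mitochondrial UMIs, the cluster held 359 DLX2 and 12 control cells.

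Per astrocyte, the DLX2 library held 2.31 neuroblasts (2.14 to 2.49) and the control library 1.15 (0.843 to 1.58), a fold of 2.00 (1.45 to 2.77). This fold differed between cells split by sex-linked UMIs: among cells with Xist and no Y-linked UMI it was 0.801 (0.532 to 1.19), with 1135 neuroblasts and 660 astrocytes in DLX2 and 88 and 41 in control. Among cells with Y-linked UMIs and no Xist it was 40.9 (9.99 to 358), resting on 2 neuroblasts and 25 astrocytes in control. Under the stricter filter the fold was 1.42. There were 0.538 and 0.203 progenitors per astrocyte, and 4.29 and 5.69 neuroblasts per progenitor. Neuroblasts without a vector UMI numbered 0.956 and 1.06 per astrocyte.

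**Figure D3:**
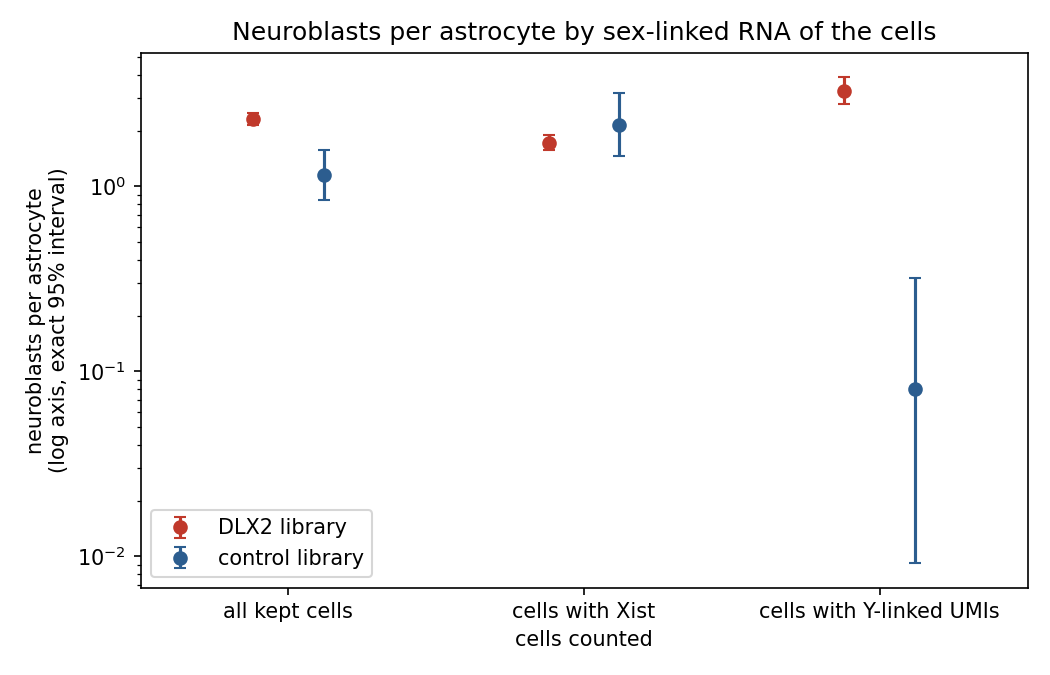
Neuroblasts per astrocyte in each library, for all kept cells and for cells split by Xist and Y-linked UMIs, on a log axis with exact 95% intervals. The values were 2.31 and 1.15 for all cells, and 1.72 and 2.15 among cells with Xist only.

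By share of cells with a UMI at 2500 UMIs, Dcx was found in 35.6% of all DLX2 and 2.20% of all control cells, against 0.652% and 0.117% of lymphocytes. Mki67, a protein of dividing cells, was in 5.71% and 3.25% of all cells, against 1.08% of DLX2 and 0 of 108 control endothelial cells, which allows up to 2.78%, and without thinning in 8.556% and 8.498%. Within progenitors the libraries lay closer, with Mki67 in 47.0% and 43.8% of cells, the control having 16 progenitors.

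The third comparison, within astrocytes, asks how astrocytes of the DLX2 library differed from those of the control library. Astrocytes of the DLX2 library had lower levels of reactive, interferon response and MHC class I genes, while genes of mature astrocyte function were alike. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament of reactive astrocytes, was 47.6 CPM in DLX2 and 335 CPM in control once mixed barcodes were removed, a control over DLX2 ratio of 7.03 (5.66 to 8.70). Among cells with Xist and no Y-linked UMI this ratio was 15.5 (11.9 to 20.2), and among cells with Y-linked UMIs and no Xist it was 0.4801 (0.152 to 1.16), an interval that includes 1. Serpina3n, a secreted protease inhibitor of reactive astrocytes, was 14.9-fold (10.9 to 20.4) higher in control, and Gbp2, an interferon-induced GTPase, 10.2-fold (7.12 to 14.6). The MHC class II genes H2-Ab1, at 16.0 (11.7 to 21.9), and Cd74, the invariant chain, at 13.3 (10.0 to 17.6), were also higher in control. Without mixed barcodes Cd74 was also 6.02-fold higher in control neuroblasts and 11.5-fold in control endothelial cells. Free immune RNA was not tested for these class II genes. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), an interferon-induced chemokine, stood at 33.2 (22.9 to 48.8), but 1 control cell held 68 of its 99 control UMIs, without which the ratio was 10.5, and 1 DLX2 cell held 31 of its 42 DLX2 UMIs.

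Of 23 reactive genes measured, 21 were at least 1.5-fold lower in DLX2 and 1 higher, with a median log2 ratio of -2.23. Of 26 interferon response genes 24 were lower and 0 higher, with a median of -1.89, and Irf7, a regulator of interferon, was 12.6-fold higher in control, 7.51-fold without the top control cell and 6.15-fold without mixed barcodes. Of 20 MHC class I and antigen processing genes 17 were lower and 0 higher, median -1.64, among them H2-Q7 at 9.91 (6.26 to 15.6) in control over DLX2, or 3.93 without mixed barcodes, while the chaperones Pdia3 and Calr had ratios of 1.17 and 1.04. No random list reached medians as low as any of these. Without mixed barcodes, 2 of 952 DLX2 and 3 of 79 control astrocytes, the medians were -1.93, -1.79 and -1.39. Thinned to 2500 UMIs, 7.19% of DLX2 astrocytes (5.60% to 9.06%) and 38.4% of control astrocytes (27.2% to 50.5%) held a Gfap UMI, against 0 of 460 and 0 of 858 lymphocytes, which allow up to 0.652% and 0.350%. Astrocytes had median depths of 5686.5 and 4937 UMIs and lymphocytes of 3424 and 3789.5. The control astrocytes were mixed by sex: among 39 Xist and 25 Y-linked cells without mixed barcodes, the control over DLX2 ratio of the summed reactive genes was 4.99 and 1.53, of the interferon genes 3.29 and 2.50, and of MHC class I genes 2.61 and 0.987. Without the top cell of each library the Y-linked ratios were 1.16 for reactive and 0.805 (0.631 to 1.01) for interferon genes.

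Homeostatic astrocyte genes had a median of -0.031, with 0 of 40 at least 1.5-fold higher and 2 lower, the potassium channel Kcnj10 at 1.55 and Mlc1 at 1.61 in control over DLX2. Neural stem cell and progenitor genes had a median of 0.33, with 8 of 23 higher, such as Egfr at 1.82 (1.15 to 3.06), and 3 lower, such as the matrix protein Thbs4, 5.78-fold higher in control. Their mean was 0.024. Egfr was found in 19.1% of DLX2 and 5.48% of control astrocytes, and in 0 lymphocytes of either library, with the same limits as for Gfap. The ratio of the Egfr shares in astrocytes, 3.48 (1.33 to 12.9), was 1.11 at the lower thinning depth and 1.52 without thinning. Neuroblast genes had a median of 0.50, 0.38 with genes at 0 in control set at their bound, and 11 of 25 were higher, such as Stmn2 with 94 DLX2 and 0 control UMIs. These genes mark another cell type, 39.1% of DLX2 and 1.96% of control cells: Stmn2 was at 16.9 and 0 CPM in astrocytes, and at 9.64 and 0 CPM in lymphocytes. Cholesterol synthesis genes had a median of 0.35, with 10 of 29 higher, such as the mevalonate pathway kinases Mvk at 4.502 (1.51 to 22.05) and Pmvk at 2.48 (1.46 to 4.57), and 1 lower. The Notch target Hes5 was at 1.73 (1.54 to 1.95), although the Notch list had a median of -0.070.

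Microglial genes, which mark another cell type, had a median of -6.17 over 16 genes and -0.37 over 7 without mixed barcodes. The complement gene C1qa was 238-fold higher in control (142 to 431) before and 29.1-fold after this removal, and Tyrobp, an immune signalling adaptor, 83.1-fold before and 2.81-fold after. Immediate early genes went from a median of -0.58 to -0.021. The 4 haemoglobin genes named as higher in DLX2, such as Hbb-bs at least 65.4-fold, lay in 1 barcode, and their list, of red blood cell and choroid genes, had a median of 6.43 over 5 genes, 3.85 with genes at 0 at their bound. The remaining medians were -0.43 for myelin, -0.52 for p53, -0.11 for cell cycle, 0.15 for GABAergic fate, -0.034 for striatal projection neuron, -0.029 for synapse, 0.079 for OPC, -0.051 for unfolded protein, 0.0032 for glycolysis, -0.14 for mitochondrially encoded and -0.57 for cilium genes. Vascular genes had too few members for a median.

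**Figure D4:**
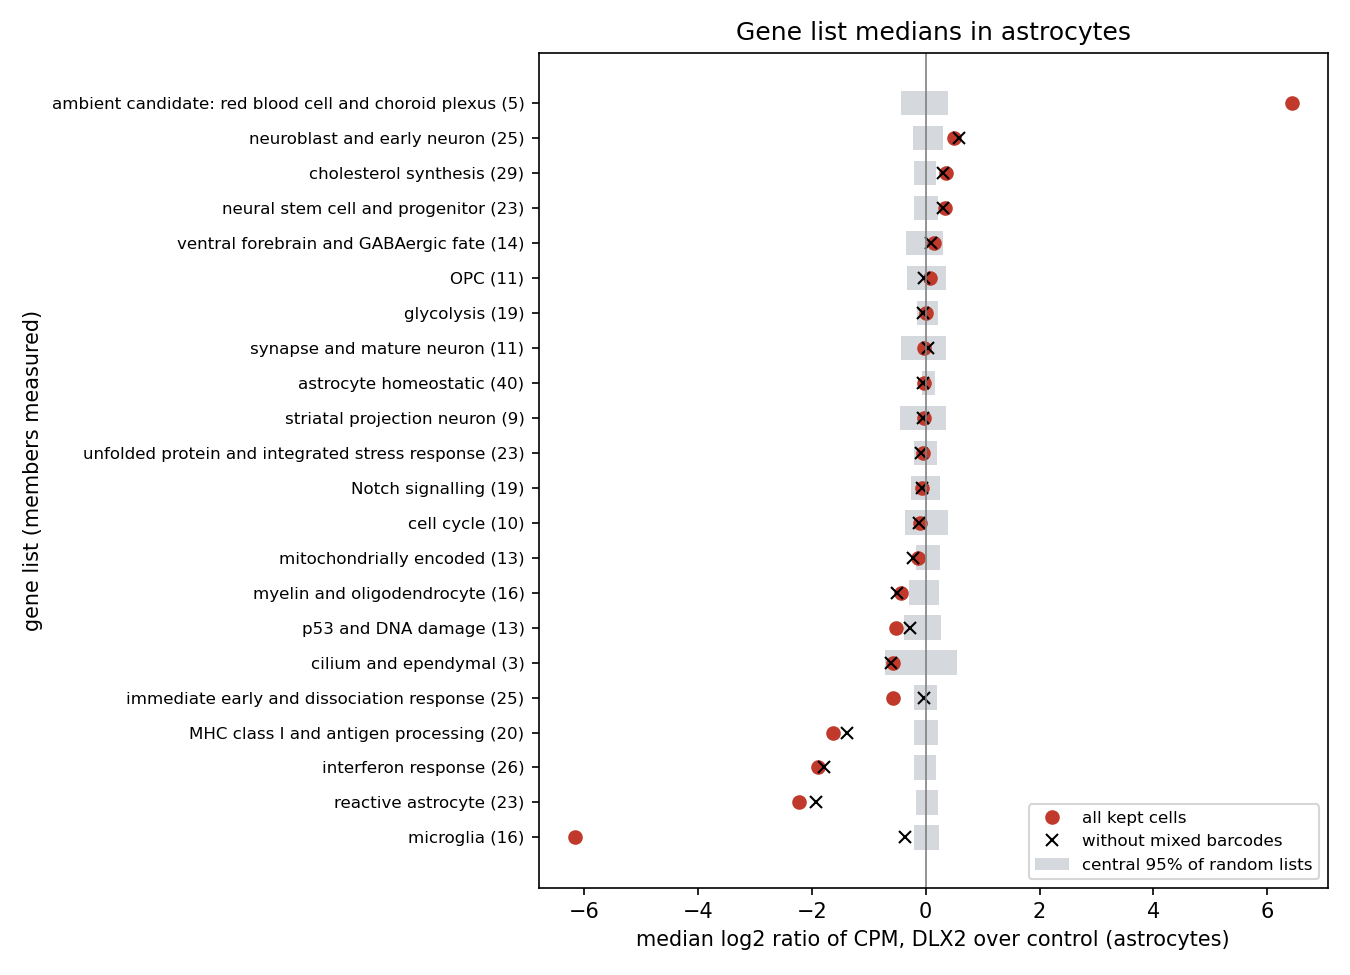
Median log2 ratio (DLX2 over control) of each gene list in astrocytes, with all kept cells and without mixed barcodes. Reactive, interferon and MHC class I genes lay at -2.23, -1.89 and -1.64, and at -1.93, -1.79 and -1.39 without mixed barcodes.

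By the size rule 199 genes were higher and 94 lower in DLX2 astrocytes, of 4807 eligible, and 227 and 51 without mixed barcodes. They were 330 and 26 under the stricter filter, and the lower count was 62 under the looser filter, 354 at a minimum of 10 UMIs and 29 at a minimum of 100. In simulated data with no difference, 87 genes passed as higher and 0 as lower, so the higher count contains many genes that counting error alone would give. Named genes higher in DLX2 included the chemokine Ccl25, at least 4.13-fold, the phosphodiesterase Pde7b, at least 3.28-fold, the protease Prss56 at 3.21 (2.02 to 5.45), the myelin gene Mbp at 4.23 (1.63 to 15.7) and Etnppl, an enzyme of phosphoethanolamine breakdown, at 2.13 (1.497 to 3.13).

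The fourth comparison asks how neuroblasts of the DLX2 library differed from those of the control library. Slc1a3, a glutamate transporter of astrocytes and radial glia, was 5.70-fold (3.60 to 9.64) higher in DLX2, Igfbp5, an insulin-like growth factor binding protein, 4.92-fold (3.55 to 7.03), Id4, an inhibitor of bHLH factors, 4.53-fold (3.22 to 6.59), and Dbi, which binds acyl-CoA, 4.32-fold (2.94 to 6.63). Astrocytes were 16.9% of DLX2 and 1.70% of control cells, and whether free astrocyte RNA raised Slc1a3 was not tested. Of neuroblasts assigned to a sex, 34.7% in DLX2 and 2.22% in control held Y-linked UMIs and no Xist. The gene ratios of neuroblasts were not split by sex. In control over DLX2, Mn1 stood at 7.52 (5.07 to 10.9), Vax1, a ventral forebrain homeobox factor, at 4.26 (2.81 to 6.25) and the corepressor Runx1t1 at 3.41 (2.85 to 4.06). Snhg11 was at 14.0, or 1.56 without 1 cell that held 73 of its 82 control UMIs, and the lymphoid gene Cd52 at 22.5, with 80.9% of its control UMIs in mixed barcodes. Car2, a carbonic anhydrase, was at 15.3 (2.73 to 606) in DLX2 over control. With each library clustered alone, the log2 ratio of Dbi turned to -1.04. In that setting no control cell was named a progenitor, against 16 in the main clustering. Control neuroblasts then numbered 106 in place of 91, so its values compare other cells. Whether this accounts for the move of Dbi was not tested.

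The vector was at 332 CPM in DLX2 and 20.6 CPM in control neuroblasts, a ratio of 16.1 (8.15 to 37.3) that depends on the doublet call and on the clustering. With called doublets kept, 1 control barcode held 383 of the 391 vector UMIs of control neuroblasts and the log2 ratio, 3.92, turned to -1.65. With each library clustered alone it was 1.01, as control neuroblasts then held 105 vector UMIs in place of 8. Of these 105, 61 lay in 1 barcode that was a progenitor in the main clustering. The ratio of the shares of cells with a vector UMI, 9.38, was 6.28 with doublets kept.

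Neuroblast genes were alike, with a median log2 ratio of 0.039 and 1 of 33 higher and 1 lower. Neural stem cell and progenitor genes had a median of -0.081 and a mean of 0.17, with 6 of 26 higher and 3 lower. Synapse and mature neuron genes had a median of -0.62, with 0 of 22 higher and 11 lower, such as the vesicle protein gene Syn2, 6.14-fold higher in control. Interferon genes had a median of -0.65, with 12 of 23 lower and 4 higher, and MHC class I genes of -0.42, with 8 of 20 lower, or -0.12 without mixed barcodes. Microglial genes, which mark another cell type, had a median of -1.96, with 0 of 11 higher and 8 lower, or -2.11 without mixed barcodes. GABAergic fate genes had a median of -0.21, with 8 of 26 lower and 1 higher. Homeostatic astrocyte genes had a median of 0.53, with 12 of 26 higher and 2 lower, or 0.12 with genes at 0 at their bound, and myelin genes of 0.77, with 7 of 14 higher and 3 lower, or -0.0029 at a minimum of 10 UMIs. By size, 227 genes were higher and 30 lower of 4423, where 139 and 0 pass in simulated data with no difference. With each library clustered alone, where no control cell was named a progenitor, 270 were higher and 209 lower. The lower count was 213 at a minimum of 10 UMIs and 4 at a minimum of 100.

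The fifth comparison covers the other classes. In oligodendrocytes, as in astrocytes, immune response genes were lower in DLX2: 28 of 28 interferon genes (median -1.86), 20 of 21 MHC class I genes (-1.72) and 14 of 15 reactive genes (-1.91), with Serpina3n 32.3-fold (22.4 to 48.5) higher in control. The secreted proteases Klk6, at 9.68 (8.29 to 11.4), and Klk8, at 1205 (216 to 47642), were also higher in control. Astrocyte genes, which mark another cell type, were higher in DLX2 oligodendrocytes, 28 of 33 with a median of 2.64, such as Sox9, a glial transcription factor, at least 27.4-fold, and Hes5 at 53.9 (14.5 to 453). Crym, a leading gene of the Igfbp4 cluster, was at 61.9 (33.4 to 130). Without mixed barcodes 1 DLX2 cell held 130 of its 482 DLX2 UMIs. Without mixed barcodes the interferon, MHC class I, reactive and astrocyte medians were -1.93, -1.79, -1.68 and 2.49. This removal took 0 of 85 DLX2 and 5 of 77 control oligodendrocytes. It is therefore no check on astrocyte RNA in the DLX2 barcodes, and barcodes with an oligodendrocyte and an astrocyte were not tested. Among cells with Y-linked UMIs, of which control had 7, the summed interferon genes had a control over DLX2 ratio of 0.865, against 3.73 among Xist cells, and the summed astrocyte genes of 1.35 (1.26 to 1.44) against 0.3597 (0.349 to 0.371). Microglial genes had a median of -5.12 over 12 genes, or -0.43 over 5 without mixed barcodes. By size 302 genes were higher and 402 lower of 5067, 513 higher at a minimum of 10 UMIs, and 99 and 159 at a minimum of 100.

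Endothelial cells had lower interferon genes, 20 of 31 with a median of -0.72, and MHC class I genes, 18 of 21 with a median of -0.82, and these medians were -0.71 and -0.79 without mixed barcodes. Among cells with Y-linked UMIs the summed interferon genes had a control over DLX2 ratio of 0.894, against 2.01 among Xist cells. The chemokine Cxcl9 was 115-fold (44.9 to 425) higher in control, and the MHC class II gene H2-Ab1 65.1-fold, or 35.2-fold without mixed barcodes. Microglial genes had a median of -5.71 over 17 genes, or -0.44 over 7 without mixed barcodes. Hbegf, a growth factor that binds Egfr, was 2.99-fold (2.16 to 4.17) higher in DLX2 without mixed barcodes, but 1 DLX2 cell held 48 of its 113 DLX2 UMIs, and without it the ratio was 1.77. The named haemoglobin genes, such as Hbb-bs at least 234-fold higher, lay mostly in 1 barcode and turned to log2 ratios from -0.92 for Hbb-bt to -0.76 for Hba-a1 with doublets kept. By size 103 genes were higher and 173 lower of 5590, or 73 and 216 under median-of-ratios scaling. The lower count was 371 with each library clustered alone, the higher count 186 with doublets kept and 191 at a minimum of 10 UMIs, and they were 13 and 66 at a minimum of 100.

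Microglia or macrophages of the DLX2 library had higher immediate early genes, with 18 of 36 higher and 0 lower and a median of 0.59, such as the heat shock genes Hspa1a at 8.44 and Hspa1b at 8.30. Genes that mark other cell types were also higher, with medians of 2.88 for neuroblast genes (19 of 23 higher, 1 lower), 1.69 for astrocyte genes (17 of 24, 0 lower) and 0.62 for stem cell and progenitor genes (12 of 20, 1 lower), or 1.54, 0.74 and 0.47 without mixed barcodes, where the immediate early median was 0.63. Without mixed barcodes, the macrophage genes F13a1, at 24.6 (19.6 to 31.1), and Retnla, at 21.3 (18.2 to 24.9), or 12.7 without the DLX2 cell that held 154 of its 380 UMIs, were higher in DLX2, while the chemokine Cxcl13 was 5.48-fold (4.15 to 7.395) and Gbp2 3.52-fold (3.06 to 4.06) higher in control. Saa3 and Chil3, at 4.497 and 3.38 in control over DLX2, turned to log2 ratios of 1.13 and 5.71 with each library clustered alone. The class pools 4 clusters with other proportions in each library: 149 DLX2 and 747 control cells, 90 and 434, 31 and 900, and 14 and 438. Cell cycle genes had a median of 1.08, or 0.42 without mixed barcodes. By size 147 genes were higher and 62 lower of 5036, or 117 and 90 under median-of-ratios scaling, which shifted all genes by -0.13. The higher count was 265 with each library clustered alone and 85 at a minimum of 100 UMIs.

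Lymphocytes had 45 genes higher and 28 lower of 5150, with the higher count at 79 under the stricter filter and at 25 under equal weight per cell or a minimum of 100 UMIs. Cell cycle genes had a median of -0.42, with 16 of 41 lower and 0 higher, such as the spindle gene Hmmr, 4.23-fold higher in control, and a median of -0.12 under equal weight per cell. The class pools 5 clusters with other proportions in each library: 123 DLX2 and 118 control cells, 39 and 129, 59 and 224, 331 and 512, and 49 and 47. Microglial genes, which mark another cell type, had a median of -0.83, with C1qa 23.3-fold (15.5 to 37.0) higher in control. Without mixed barcodes C1qa was 22.9-fold higher, and 1 control cell held 315 of its 952 control UMIs. Microglia or macrophages were 5.05% of DLX2 and 54.2% of control cells, and their free RNA was not tested in lymphocytes. The astrocyte list had a median of 1.56, or 0.11 without mixed barcodes.

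**Figure D5:**
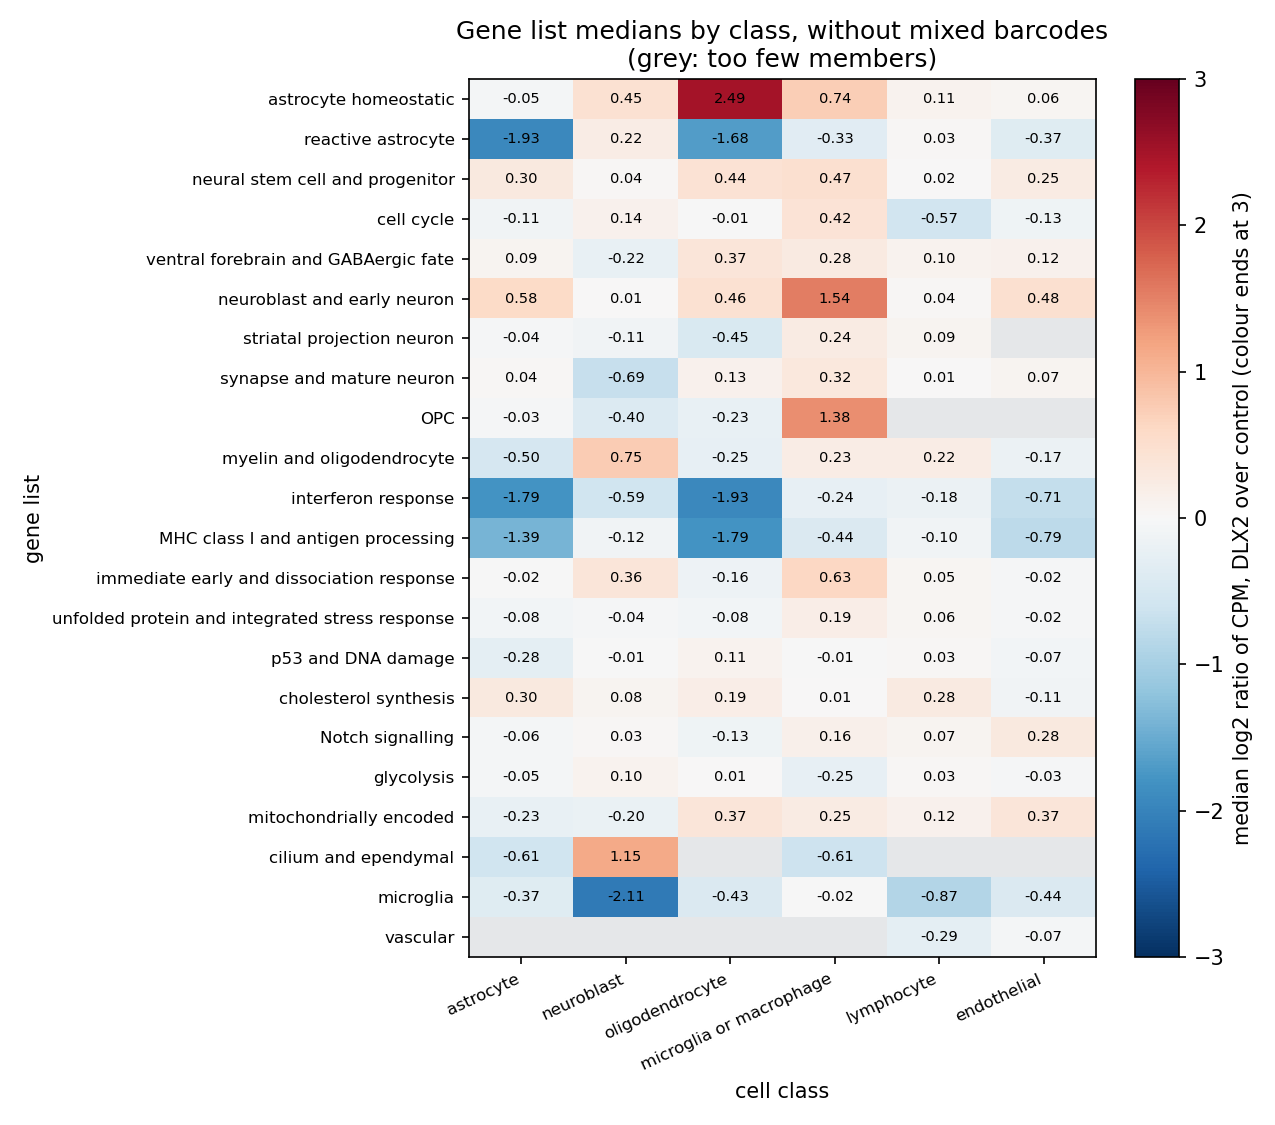
Median log2 ratio (DLX2 over control) of each gene list, in rows, for each class, in columns, without mixed barcodes (grey where too few members were measured). Interferon genes lay at -1.79 in astrocytes, -1.93 in oligodendrocytes, -0.71 in endothelial cells and -0.24 in microglia or macrophages.

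The last comparison sums all kept cells of each library and needs no cluster. In the DLX2 library, 33 of 33 neuroblast genes were at least 1.5-fold higher (median 3.88), as were 28 of 34 GABAergic fate genes (3.45). So were 41 of 42 cell cycle genes (2.24) and 37 of 40 astrocyte genes (3.34). The median of all genes, 0.70, already lay above this 1.5-fold cut, and that of striatal projection neuron genes lay below the median of all genes. Examples are Sp8, a factor of interneuron development, at 53.2, and Egfr at 35.4. Of 24 microglial genes 23 were lower (median -3.03), with C1qa 12.4-fold higher in control, as were 17 of 20 cilium genes (-2.30), such as Tmem212, at least 406.5-fold. Dio2, an enzyme that activates thyroid hormone, was 139-fold (114 to 172) higher in DLX2. By size 2566 genes were higher and 930 lower of 7428, but 1280 and 1612 under median-of-ratios scaling, which shifted all genes by a log2 of -0.67, the median of all genes being 0.70. These sums follow the proportions of cell types.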

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

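Of the tests here, that of free RNA of microglia or macrophages was set before its result was seen, and all the others were chosen after. The DLX2 over control fold of neuroblasts per astrocyte was 0.801 (0.532 to 1.19) among cells with Xist and no Y-linked UMI, an interval that includes 1, and 40.9 (9.99 to 358) among cells with Y-linked UMIs and no Xist, resting on 2 control neuroblasts. The difference between the 2 was not tested. In the control library, cells with Y-linked UMIs were 37.9% of the astrocytes assigned to a sex but 2.22% of the neuroblasts, and in the DLX2 library they were 21.8% and 34.7%.

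Neuroblasts made up more of the DLX2 library. At equal depth, vector UMIs were 9.38 times as frequent in DLX2 as in control neuroblasts. For neuroblasts that held a vector UMI, this cannot decide on resident cells carried along in the dissection. The DLX2 and control injections need not have reached the same cells. In control the vector was found in OPCs and ependymal cells, which were rare or absent in DLX2, and the control vector shares only parts of the added sequence. Free vector RNA is argued against, since DLX2 neuroblasts held a vector UMI 8.93 times as often as lymphocytes of that library. Endothelial cells of that library held a vector UMI about as often as neuroblasts, so such a UMI does not by itself mark neuronal lineage cells. Infection of resident neuroblasts, or of resident progenitors, of which 51.9% in DLX2 and 31.25% in control held a vector UMI, was not tested and stays open. For neuroblasts without a vector UMI, the number per astrocyte had a ratio of 0.899 (0.644 to 1.25) between the libraries. Low capture also leaves cells without a vector UMI. That ratio pools the sexes. Among Xist cells, 633 of 1135 DLX2 and 6 of 88 control neuroblasts held a vector UMI, beside 660 and 41 astrocytes. Among cells with Y-linked UMIs it was 379 of 602 and 0 of 2, beside 184 and 25 astrocytes. The remaining neuroblasts per astrocyte were thus fewer in DLX2 among Xist cells and more among cells with Y-linked UMIs. The pooled ratio therefore cannot decide on resident cells, which stay open for these neuroblasts. Among Xist cells the neuroblast share of neural cells was 2.09 (1.68 to 2.62) times higher in DLX2. This argues against the sexes of the mice as the whole cause for that share alone. Over astrocytes, the Igfbp4 cluster, progenitors and neuroblasts, the ratio was 0.833 (0.6699 to 1.05) among Xist cells. Among cells with Y-linked UMIs it was 6.79 (1.87 to 56.2). The fold per astrocyte was 0.801 and 40.9 in these groups. A mix of sexes alone would leave no difference within either sex, but the values with Y-linked UMIs rest on 2 control neuroblasts. Whether the sexes account for the fold per astrocyte therefore stays open.

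Reactive, interferon and MHC class I genes were lower in DLX2 astrocytes. Barcodes that held an astrocyte and an immune cell are not the whole cause, since without them the median nearest to 0 of the 3 lists was -1.39. Free RNA of microglia or macrophages, gauged by C1qa, C1qb and C1qc, accounted for a median of 1.15% of the difference over 53 genes, and at most 18.2%. Free RNA of lymphocytes and other immune cells was not tested. Whether the difference belongs to control mice with Xist, and not to the control library as a whole, remained open for reactive and interferon genes: among cells with Y-linked UMIs the control over DLX2 ratios were 1.53 and 2.50, but 1.16 and 0.805 without the top cell of each library, so they cannot be told apart with 25 such control cells. For MHC class I genes the ratio there was 0.987 (0.851 to 1.14) against 2.61 in Xist cells, which is consistent with a difference in some of the control mice, and an effect of DLX2 remains open as a hypothesis.

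Lymphocytes held tdTomato UMIs, although the reporter is meant for astrocytes. Without thinning, so did 137 of 284 DLX2 and 1243 of 2519 control microglia or macrophages, for which no cause was tested. Free tdTomato RNA is argued against, since at equal depth lymphocytes held a tdTomato UMI at least 3.79 times as often as endothelial cells in each library. Barcodes with an astrocyte and a lymphocyte are argued against as well: tdTomato in lymphocytes reached 59.4% and 51.2% of its astrocyte level in DLX2 and control, while 15 astrocyte markers reached medians of 0.361% and 0.0335%, at most 0.00607 of the tdTomato percentage. Lentiviral reads counted on the tdTomato sequence would keep it in 1 ratio to the vector, but that ratio was at least 72.4 times higher in lymphocytes than in endothelial cells. Expression of the reporter in these lymphocytes stays open as a hypothesis, and the sort would enrich such cells.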

How the results depend on the processing

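The alternatives without mixed barcodes, without the top cell, over neural cells, over astrocytes, the Igfbp4 cluster, progenitors and neuroblasts, among cells with a tdTomato UMI, among cells with Xist and no Y-linked UMI and with related classes counted as other classes were chosen after seeing the data, and the others before the data were examined. No paired analysis was possible because each group has 1 library. Values moved by less than their counting interval, gene counts by less than 1.5 times, and list medians by less than the spread of random lists in 112 of 138 share ratios, 10 of 12 folds of neuroblasts per astrocyte, 28 of 32 ratios of shares of cells with a UMI, 4 of 6 CPM ratios, 93 of 118 gene counts, 574 of 744 log2 ratios of named genes and 734 of 876 list medians. Among all of these, 17 log2 ratios of named genes, 93 list medians, 4 share ratios, 2 ratios of shares of cells with a UMI and 1 fold lay on the other side of no difference from the value in the report. Of these 93 medians, 3 had been at least 1.5-fold from no difference. The summed UMIs limit the astrocyte and neuroblast comparisons most, with 441611 and 387546 in control. Each library clustered alone gave no ratio for the Igfbp4 cluster, progenitors, mural cells and OPCs, which 1 library then lacked. Cells with Xist gave none for neurons, and ependymal cells, of which DLX2 held 0, had no ratio to vary. The minimum of 100 UMIs left no cilium median in astrocytes, neuroblasts and microglia or macrophages, no projection neuron, synapse or Notch median in oligodendrocytes, no synapse median in lymphocytes and no synapse or OPC median in endothelial cells. Without mixed barcodes no median was left for red blood cell and choroid genes in astrocytes and endothelial cells, nor for OPC genes in endothelial cells. The values that moved further follow, except 153 log2 ratios of named genes that moved without a change of sign, and the cause was not tested, apart from the vector in neuroblasts, where with doublets kept 1 control barcode brought 383 of the 391 vector UMIs of control neuroblasts. Under the looser filter, genes past the size rule numbered 62 lower in astrocytes. Under the stricter filter, ratios of shares or cell numbers, DLX2 over control, were 15.2 for astrocytes, 26.6 for the Igfbp4 cluster and 1.42 for neuroblasts per astrocyte. Genes past the size rule numbered 330 higher in astrocytes, 26 lower in astrocytes and 79 higher in lymphocytes. With doublets kept, ratios of shares or cell numbers, DLX2 over control, were 0.558 for lymphocytes. Ratios were 2.33 for the vector's CPM in the whole library. Genes past the size rule numbered 186 higher in endothelial cells. Log2 ratios that changed sign were -1.65 for the vector in neuroblasts, -0.81 for Hbb-bs in endothelial cells, -0.76 for Hba-a1 in endothelial cells, -0.89 for Hba-a2 in endothelial cells and -0.92 for Hbb-bt in endothelial cells. At a clustering resolution of 0.5, ratios of shares or cell numbers, DLX2 over control, were 0.586 for oligodendrocytes. With genes centred within each library, ratios of shares or cell numbers, DLX2 over control, were 0.586 for oligodendrocytes and 0.0442 for microglia or macrophages. From clustering each library alone, ratios of shares or cell numbers, DLX2 over control, were 0.195 for microglia or macrophages and 0.628 for lymphocytes. Genes past the size rule numbered 209 lower in neuroblasts, 265 higher in microglia or macrophages and 371 lower in endothelial cells. In that setting control neuroblasts numbered 106 and no control cell was named a progenitor. Log2 ratios that changed sign were -1.04 for Dbi in neuroblasts, 1.13 for Saa3 in microglia or macrophages and 5.71 for Chil3 in microglia or macrophages. With related classes counted as other classes, ratios of shares or cell numbers, DLX2 over control, were 0.107 for microglia or macrophages. Over neural cells, ratios of shares or cell numbers, DLX2 over control, were 1.26 for astrocytes, 10.2 for the Igfbp4 cluster, 3.36 for progenitors, 2.53 for neuroblasts, 0.0735 for neurons, 0.00677 for OPCs and 0.116 for oligodendrocytes. Over astrocytes, the Igfbp4 cluster, progenitors and neuroblasts, ratios of shares or cell numbers, DLX2 over control, were 0.545 for astrocytes, 4.4 for the Igfbp4 cluster, 1.45 for progenitors and 1.09 for neuroblasts. Among cells with a tdTomato UMI, ratios of shares or cell numbers, DLX2 over control, were 0.0708 for microglia or macrophages, 0.397 for lymphocytes, 0.51 for endothelial cells and 0.642 for mural cells. Among cells with Xist and no Y-linked UMI, ratios of shares or cell numbers, DLX2 over control, were 21.4 for astrocytes, 0.59 for lymphocytes and 0.801 for neuroblasts per astrocyte. Over all barcodes of the matrix, ratios were 2.4 for the vector's CPM in the whole library. At the lower thinning depth, ratios were 1.11 for Egfr in astrocytes and 2.21 for Mki67 in the whole library. Without thinning, ratios were 13.2 for Dcx in the whole library and 1.01 for Mki67 in the whole library. Under median-of-ratios scaling, genes past the size rule numbered 1280 higher in the whole library and 1612 lower in the whole library. List medians in microglia or macrophages were interferon -0.31, immediate early 0.46 and microglia -0.20. Those in the whole library were homeostatic 2.67, reactive -1.15, stem cell 1.54, cell cycle 1.57, GABAergic 2.78, neuroblast 3.21, projection neuron -0.49, synapse 1.34 and OPC -1.43. Also there, myelin -1.03, interferon -1.91, MHC class I -2.09, immediate early -1.54, unfolded protein -0.57, p53 -0.28, cholesterol 0.62, Notch 0.63 and glycolysis -0.85. Also there, microglia -3.70 and vascular -0.60. Under equal weight for each cell, genes past the size rule numbered 25 higher in lymphocytes. List medians in astrocytes were MHC class I -1.35, microglia -4.79 and red blood cell and choroid 5.92. Those in oligodendrocytes were homeostatic 1.97, immediate early -0.43, cholesterol 0.35 and microglia -3.85. Those in microglia or macrophages were homeostatic 1.14 and cell cycle 0.67. Those in lymphocytes were cell cycle -0.12 and microglia -0.67. Those in endothelial cells were neuroblast 0.50 and microglia -4.24. Those in the whole library were homeostatic 2.78 and cell cycle 1.61. With means in place of medians, list medians in astrocytes were stem cell 0.024, neuroblast 0.95, immediate early -1.10, microglia -4.91 and red blood cell and choroid 5.66. Those in neuroblasts were homeostatic 0.76, stem cell 0.17, OPC 0.18, interferon -0.34, MHC class I -0.66, immediate early -0.35 and unfolded protein -0.22. Those in oligodendrocytes were homeostatic 2.29, projection neuron -1.46, OPC 0.28, immediate early -0.55, unfolded protein 0.18, Notch 0.39, glycolysis 0.48 and microglia -3.92. Those in microglia or macrophages were reactive 0.19, stem cell 1.59, GABAergic 1.64, myelin 0.62, immediate early 0.72 and microglia 0.16. Those in lymphocytes were homeostatic 1.98, reactive -0.20, stem cell 0.49, cell cycle -0.57, neuroblast 0.55, immediate early 0.058, mitochondrial -0.017 and microglia -1.38. Those in endothelial cells were homeostatic 0.46, reactive -0.72, cell cycle 1.14, GABAergic 0.72, neuroblast 0.96, OPC 1.81, interferon -0.94, microglia -4.43 and red blood cell and choroid 6.89. Those in the whole library were homeostatic 2.91, GABAergic 2.79 and red blood cell and choroid 4.10. At a minimum of 10 UMIs, genes past the size rule numbered 354 lower in astrocytes, 213 lower in neuroblasts, 513 higher in oligodendrocytes and 191 higher in endothelial cells. List medians in astrocytes were immediate early -1.09. Those in neuroblasts were myelin -0.0029 and cilium -0.31. Those in oligodendrocytes were reactive -1.59, cell cycle 0.46, GABAergic 1.63 and neuroblast 0.92. Those in microglia or macrophages were homeostatic 2.25 and stem cell 1.76. Those in lymphocytes were homeostatic 2.81, stem cell 0.23, GABAergic 0.59, neuroblast 2.55, projection neuron -0.39 and microglia -0.56. Those in endothelial cells were cell cycle 0.81, GABAergic 1.22, neuroblast 1.75 and microglia -4.94. Those in the whole library were red blood cell and choroid 5.66. At a minimum of 100 UMIs, genes past the size rule numbered 29 lower in astrocytes, 4 lower in neuroblasts, 99 higher in oligodendrocytes, 159 lower in oligodendrocytes, 85 higher in microglia or macrophages, 25 higher in lymphocytes, 13 higher in endothelial cells and 66 lower in endothelial cells. List medians in astrocytes were myelin -0.16, interferon -1.66, MHC class I -1.21 and microglia -4.53. Those in neuroblasts were myelin 1.55, immediate early 0.17 and microglia -0.66. Those in oligodendrocytes were homeostatic 1.83. Those in microglia or macrophages were homeostatic 1.18, cell cycle 0.69, GABAergic 0.52, neuroblast 1.37 and OPC 2.15. Those in lymphocytes were homeostatic 0.093, neuroblast -0.12, myelin 0.40 and microglia -0.61. Those in endothelial cells were p53 0.25 and microglia -3.68. Without the mixed barcodes, genes past the size rule numbered 51 lower in astrocytes and 68 higher in endothelial cells. Log2 ratios that changed sign were -2.23 for Hbb-bs in astrocytes, -3.81 for Hba-a1 in astrocytes, -3.81 for Hba-a2 in astrocytes and -3.81 for Hbb-bt in astrocytes. List medians in astrocytes were reactive -1.93, MHC class I -1.39, immediate early -0.021 and microglia -0.37. Those in neuroblasts were reactive 0.22, MHC class I -0.12 and immediate early 0.36. Those in oligodendrocytes were microglia -0.43. Those in microglia or macrophages were homeostatic 0.74, cell cycle 0.42, GABAergic 0.28 and neuroblast 1.54. Those in lymphocytes were homeostatic 0.11, cell cycle -0.57 and immediate early 0.049. Those in endothelial cells were cell cycle -0.13, neuroblast 0.48 and microglia -0.44. Those in the whole library were red blood cell and choroid -1.70. Without the top cell of the higher library, log2 ratios that changed sign were -2.07 for Hbb-bs in astrocytes, -3.65 for Hba-a1 in astrocytes, -3.65 for Hba-a2 in astrocytes, -3.65 for Hbb-bt in astrocytes and -1.03 for Gzmc in lymphocytes.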

Other observations

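Of the tests here, that of the vector's part in neuroblast genes was set before its result was seen, while the split by sex was chosen after. Besides lymphocytes, microglia and macrophages, the sorted cells held immune clusters that the marker sets did not name. A cluster led by Xcr1 and Clec9a, genes of cross-presenting dendritic cells, had 63 DLX2 and 87 control cells. A cluster led by Ccl22 and Ccr7, genes of migrating dendritic cells, had 47 and 133, and one led by Plet1, Epcam and Ccl17 had 90 and 195. Siglech and Ccr9, found in plasmacytoid dendritic cells, led a cluster of 5 and 41 cells. Igkc and Jchain, genes of antibody-secreting cells, led one of 41 and 56, and the mast cell genes Mcpt2 and Cpa3 one of 12 and 1. All these clusters together were 4.59% of DLX2 and 11.0% of control cells.

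The libraries differed in the sexes of the cells. Of cells assigned to a sex, 30.8% in DLX2 and 3.42% in control held Y-linked UMIs and no Xist. In the control library none of the 53 ependymal cells and none of the 16 progenitors did, and 0.511% of the lymphocytes. In DLX2 it was 44.2% of progenitors and 42.0% of the Igfbp4 cluster. In oligodendrocytes, the control over DLX2 ratio of the summed reactive genes was 3.83 among Xist cells and 1.02 among cells with Y-linked UMIs, and of MHC class I genes 3.28 and 1.04. In endothelial cells the ratios of MHC class I genes were 1.78 and 0.976.

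The hypothesis that the vector raises the genes higher in DLX2 neuroblasts was tested within the DLX2 library. Of the 5 named genes other than the vector, 3 were at least 1.5-fold higher in cells with a vector UMI than in those without: Igfbp5 at 2.94, Dbi at 2.22 and Car2 at 1.83, while Id4 was at 1.47 and Slc1a3 at 0.853. In DLX2 cells without a vector UMI the 5 genes were from 2.17-fold (Igfbp5) to 9.91-fold (Car2) above control neuroblasts, a comparison that shares its control cells with the choice of the genes and decides nothing. The median depths were 4421 UMIs with and 3536.5 UMIs without a vector UMI, and the absence of a vector UMI at such depths does not show that a cell lacks the vector. The neuroblast clusters were pooled, and cells with and without a vector UMI were not matched by cluster. The comparison therefore cannot separate an effect of the vector from other differences between these cells.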
